A study of Homo sapiens with 12 samples.

How the data were processed

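Messenger RNA was sequenced from 12 libraries of 2 hepatocellular carcinoma cell lines, Hep3B and Huh7. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was captured on beads and fragmented by heat, and the libraries were sequenced on an Illumina NovaSeq X Plus. Per the submitters' processing notes, reads were handled with fastp 0.18.0 and the genome build was hg38. The aligner, the quantification tool and the gene annotation are not given in the sources used here.

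The authors deposited 1 table of TPM for 20307 Ensembl gene identifiers in 12 columns, and every column summed to 1000000. TPM does not record sequencing depth. The depth of each library was not estimated, and no counting interval or detection floor was derived. Samples were assigned to 6 groups of 2 libraries from the treatment and cell line in their labels, and the replicate names A1 and B1 came from their titles. The labels give no exposure time, no lenvatinib dose for the combination, and no statement that A1 and B1 came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

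Gene symbols were taken from a reference table of gene names, and from GENCODE 29 (GRCh38) where that table gave none. A symbol was found for 19702 identifiers. GENCODE 29 held 20092 of the identifiers and classed 19712 as protein coding. Where several tested identifiers shared a symbol (26 cases), the one with the highest mean kept it. Coordinates are on GRCh38, 1-based. Length and GC content of the longest annotated transcript were available for 13573 of the tested genes (99.5%).

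Values were analysed as log2(TPM + 1) for the 13645 genes with TPM of at least 1 in at least 2 of the 12 libraries. Every fold change is on this scale, which understates the change of genes with low TPM. limma 3.58.1 in R 4.3.3 was fitted with an intensity trend and a mean per group on all 12 libraries, without a replicate block, which left 6 residual degrees of freedom and a prior of 2.91. With 2 libraries per group the spread had to be shared over all groups. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333 (two-sided), so no gene was tested that way. The median standard error of a log2 fold change was 0.29, and that of a difference between fold changes was 0.41. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 8 comparisons. These were lenvatinib, WWL70 and their combination each against the Hep3B control, the combination against each single compound, the interaction of both compounds, resistant against control Huh7, and the difference between that last effect and the Hep3B lenvatinib effect.

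The groups, tests, covariates, 50 gene lists covering 881 genes and the rule for naming genes were chosen before the data were examined. Lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, which made 392 tests. A list of endothelial markers had 2 tested members and so had no test. Members were also counted as past the threshold when adjusted over the list alone. Camera with an estimated correlation and fry, directional and mixed, were the alternatives. Fry asks whether a list's own genes move and does not compare them with other genes.

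Genes were named by this rule. In each comparison ABHD6, FIS1, DNM1L and LDHA were reported whatever their result. The 6 largest rises and 6 largest falls were taken among genes past the threshold with a mean TPM of at least 5 in the higher group, the same direction in all 4 cross pairs of libraries and a symbol that is more than an identifier. Up to 4 members with the smallest adjusted p came from each list with a camera call or at least 3 members past the threshold, for at most 6 lists by camera p. Lenvatinib targets with TPM of at least 1 were added. For the combination against WWL70 and for the interaction, only the first 2 parts applied, with 3 genes a side. Other genes were named after their values were seen. These were APOC3, TF, CREB3L3, VTN, BCL2L1, NRG1, RASD1 and HAL with lenvatinib, OASL with WWL70, and the identifier ENSG00000285508 in the combination and the interaction. In resistant cells they were the examples from lists outside the first 6, and the genes shared with or opposite to lenvatinib. Some genes that the rule or a count includes are not reported here.

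The alternatives chosen in advance were pseudocounts of 0.1 and 5, no filter on low values, a filter at TPM 5, median-ratio scaling, quantile normalization, rescaling without the 50 most abundant and the mitochondrially encoded genes, limma without trend, limma with robust hyperparameters, a fit within each cell line, the replicate letter as a block, each library left out in turn, an adjusted p under 0.01, and an absolute log2 fold change of at least 1. Others were added after seeing the data: leaving out the 3 A1 libraries of the groups exposed to or resistant to lenvatinib, limma's array weights, and removing from each library a trend on transcript length and GC content (splines with 3 degrees of freedom). A fit with the first component of the residuals as a covariate was also tried after seeing the data and was left out, because that component is unrelated to the groups by construction and can only shrink the error. Lists of 28 enterocyte and 13 intestinal identity genes were also added after seeing the data. Overlap between comparisons that share control libraries was set beside 100 simulated draws of unchanged groups. Other splits of the samples were not counted, because no comparison had 3 libraries per group.

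The code was tested on simulated data built from the 13645 tested genes with 200 genes changed. The tested acute phase genes were also raised by 1 on the log2 scale, and were not counted among the false calls. For lenvatinib against control the code recovered 20.9% of 2-fold, 67.2% of 4-fold and 92.4% of 8-fold changes, with 7 false calls among 132. For WWL70 against control the shares were 19.4%, 67.2% and 81.8%, with 9 false calls among 125. For the combination against control they were 26.9%, 65.7% and 81.8%, with 8 among 127, and for resistant against control Huh7 they were 25.4%, 73.1% and 89.4%, with 8 among 139. These draws gave all libraries the same independent spread per gene. In the data, A1 minus B1 had an SD of 0.973 in the combination against 0.258 in Hep3B controls. The first component of the residuals held 79.15% of their variance. The rates therefore check the code and may not hold for the calls in these data. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 in Python 3.11.15.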

Results

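Gene expression was measured as TPM in 12 mRNA sequencing libraries of Hep3B and Huh7, established human hepatocellular carcinoma lines. Hep3B cells formed 4 groups: control, lenvatinib at 20 µM, WWL70 at 20 µM, and WWL70 at 20 µM plus lenvatinib at a dose the labels do not give. Huh7 cells formed a control group and a lenvatinib-resistant group. Each group held 2 libraries, named A1 and B1. Lenvatinib inhibits receptor tyrosine kinases of the VEGF, FGF and PDGF families, and WWL70 is a carbamate inhibitor of ABHD6, a serine hydrolase that breaks down monoacylglycerols. Levels below are mean TPM ± SD (n = 2), fold changes are on the log2(TPM + 1) scale with SE where given, and adjusted p-values come from limma. Sequencing depth is not recorded by TPM and was not estimated.

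Between 14602 and 15474 genes were above 0 in each library. The 2 libraries of a group differed by a median of 0.114 (log2) in Hep3B controls, 0.134 with WWL70 and 0.115 in Huh7 controls, against 0.242 with lenvatinib, 0.755 with the combination and 0.324 in resistant cells. The combination library A1 stood apart from the others, with a median TPM over all genes of 2.96 against 6.32 in B1. Ribosomal protein genes of the fixed list took 5.96% of its TPM against 2.85% in B1, and mitochondrially encoded genes took 12.6% against 19.3%. Across genes, the deviation of combination A1 from the Hep3B control mean had a Spearman correlation of -0.523 with transcript length. In combination B1 it was 0.00118. Long transcripts therefore tended to be lower in A1. On GRCh38, ABHD6 (ENSG00000163686) lies on chromosome 3 at 58237506 to 58295693, FIS1 (ENSG00000214253) on chromosome 7 at 101239458 to 101252316, DNM1L (ENSG00000087470) on chromosome 12 at 32679200 to 32745650, and LDHA (ENSG00000134333) on chromosome 11 at 18394388 to 18408425. ABHD6 is the target of WWL70, FIS1 and DNM1L act in mitochondrial fission, and LDHA converts pyruvate to lactate.

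The first comparison asked how Hep3B cells differed after lenvatinib alone. HPX (chromosome 11, 6431049 to 6442617), which encodes the haem-binding plasma protein hemopexin, rose from 13.7 ± 0.337 to 204 ± 54.3 TPM (log2 3.78, SE 0.29, adjusted p = 0.00129, limma). APOA1 (chromosome 11, 116835751 to 116837950), the main protein of high-density lipoprotein, rose from 223 ± 1.20 to 2496 ± 425 TPM (log2 3.47, SE 0.47, adjusted p = 0.00876). NPPB (chromosome 1, 11857464 to 11858931), the B-type natriuretic peptide gene, rose from 0.841 ± 1.19 to 44.7 ± 10.7 TPM (log2 4.78, SE 0.52, adjusted p = 0.00401). NTS (chromosome 12, 85874295 to 85882992), which encodes neurotensin, fell from 555 ± 65.3 to 74.6 ± 17.3 TPM (log2 -2.89, SE 0.20, adjusted p = 0.00092). The hepatic uptake transporter gene SLCO1B3 fell from 25.9 ± 0.392 to 1.41 ± 0.042 TPM (log2 -3.48, SE 0.31, adjusted p = 0.00206). Among the largest changes were also rises of LYPD1 (log2 3.51), CBLN2 (3.50) and the fetal cytochrome gene CYP3A7 (3.37), and falls of LOX (-3.25), S100P (-3.13), CDKN2B (-3.12) and SPINK1 (-2.92).

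The study's own genes did not pass the threshold with lenvatinib. The pooled spread includes the combination, whose libraries differed by a median of 0.755 (log2), against 0.242 with lenvatinib and 0.114 in controls. That spread is therefore wide for this comparison, and a gene that did not pass is not shown to be unchanged. ABHD6 stood at 7.84 ± 0.193 TPM against 8.08 ± 0.211 in controls (log2 -0.04, adjusted p = 0.991, limma), FIS1 at 56.7 ± 0.813 against 50.7 ± 0.892 (0.16, adjusted p = 0.863), and DNM1L at 40.8 ± 8.34 against 45.2 ± 3.70 (-0.16, adjusted p = 0.935). LDHA stood at 279 ± 31.3 against 403 ± 22.2 TPM (log2 -0.54, SE 0.14, adjusted p = 0.114). Among the 14 tested mitochondrial fission genes, the 12 fusion genes and the 24 genes of glycolysis and lactate, limma called 0 members, with 1, 1 and 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.944, 0.903 and 0.688). Of the receptors lenvatinib inhibits, FGFR4 was the most abundant, at 253 TPM against 258 in controls (adjusted p = 0.974), and PDGFRB stood at 2.21 against 9.95 TPM (log2 -1.78, adjusted p = 0.0725).

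Of 19 tested endoplasmic reticulum chaperone and unfolded protein response genes, 5 fell over all genes and 10 when adjusted over the list alone (camera adjusted p = 1.11e-10, and adjusted p = 0.199 with an estimated correlation). HSPA5, the chaperone BiP, fell from 819 ± 13.1 to 369 ± 26.4 TPM, HSP90B1 from 1083 ± 48.2 to 472 ± 16.7 and HYOU1 from 182 to 81.4. Of 29 genes of the list ATF4 and integrated stress, 6 fell, 14 adjusted over the list alone (camera adjusted p = 1.11e-10, and adjusted p = 0.0546 with an estimated correlation). They included ASNS, which makes asparagine (346 ± 4.04 to 156 ± 4.12 TPM), PSAT1 of serine synthesis (663 ± 5.55 to 283 ± 3.18) and DDIT4 (128 to 38.9). Of 22 G2 and M phase genes, CCNB2, a mitotic cyclin, fell from 151 ± 2.01 to 83.2 ± 6.07 TPM, and 5 passed when adjusted over the list alone (camera adjusted p = 7.93e-09, and adjusted p = 0.413 with an estimated correlation). PLK1 stood at 83.0 against 139 TPM without passing (adjusted p = 0.0937).

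Of 20 genes that report MAPK output, 3 fell, and 1 rose and 8 fell when adjusted over the list alone (camera adjusted p = 0.00116, and adjusted p = 0.413 with an estimated correlation). DUSP6, an ERK phosphatase (chromosome 12, 89347232 to 89353271), fell from 82.0 ± 1.49 to 11.8 ± 4.06 TPM (log2 -2.73, SE 0.39, adjusted p = 0.0112, limma), ETV4 from 50.2 to 15.7 and SPRY2 from 25.4 to 9.49. Of 16 genes of the list NF-kB and chemokines, 4 rose, and 9 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.47e-06, and adjusted p = 0.199 with an estimated correlation). NFKBIA rose from 55.9 ± 1.09 to 117 ± 4.98 TPM, LTB from 11.1 ± 1.76 to 58.4 ± 6.11 and CXCL8, the neutrophil chemokine, from 13.8 ± 4.83 to 56.7 ± 1.66. Of 33 hepatocyte function genes, 6 rose and 12 rose and 4 fell when adjusted over the list alone, among them TF, which encodes transferrin (2255 ± 157 to 6354 ± 254 TPM), APOC3 (20.4 ± 1.75 to 139 ± 15.9) and VTN (473 ± 15.5 to 1589 ± 294). That list's test did not pass (camera adjusted p = 0.063), and its median log2 change was -0.02 while its mean was 0.31. Of 23 genes of fatty acid oxidation and PPARA targets 4 rose, among them CREB3L3, a transcription factor of fasting (5.01 to 12.9 TPM), as did 4 adjusted over the list alone (camera adjusted p = 0.00894, and adjusted p = 0.413 with an estimated correlation). With median-ratio scaling the adjusted p of fatty acid oxidation and PPARA targets was 0.053, the highest of the alternatives at the preset correlation, which began at 0.00505. BCL2L1, which restrains apoptosis, fell from 266 ± 3.05 to 165 ± 13.6 TPM (adjusted p = 0.0377).

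In all, 338 genes passed with lenvatinib, of which 188 rose and 150 fell, 262 of them by at least 1 on the log2 scale, and 1824 genes were at an unadjusted p under 0.05 where 682 would be by chance. In 59.1% of tested genes the 2 groups did not overlap, where chance gives 33.3%. With rescaling without the 50 most abundant genes the split was 219 up and 106 down. The count was 30 or 28 without Hep3B control A1 or B1, 28 or 45 without lenvatinib A1 or B1, 194 without either WWL70 library, 139 without either Huh7 control library, and 1645 or 1649 without combination A1 or B1. Of the 37 named genes past the threshold, CBLN2, HPX, LYPD1, NTS and SLCO1B3 stayed past it with each of the 12 libraries left out in turn.

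The second comparison asked what the ABHD6 inhibitor did alone. With WWL70, 2 genes passed the threshold over all genes. OASL (chromosome 12, 121019111 to 121039242), an interferon-induced antiviral gene, rose from 0.128 ± 0.016 to 3.48 ± 0.243 TPM (log2 1.99, SE 0.14, adjusted p = 0.00207, limma). Its level is below 5 TPM and it was named after its values were seen. ABHD6 itself stood at 10.4 ± 0.434 against 8.08 ± 0.211 TPM (log2 0.33, SE 0.30, adjusted p = 1), LDHA at 389 ± 37.9 against 403 ± 22.2 (log2 -0.05), FIS1 at 46.4 against 50.7 and DNM1L at 43.3 against 45.2, each with an adjusted p of 1.

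Of 16 genes of the list NF-kB and chemokines, limma called 0 over all genes, 9 fell when adjusted over the list alone, and 9 had an unadjusted p under 0.05 (median log2 -0.85, camera adjusted p = 2.77e-20). The call held with an estimated correlation (adjusted p = 0.0292). CXCL1 stood at 3.10 ± 1.56 against 17.3 ± 3.56 TPM (log2 -2.20, SE 0.30, adjusted p = 0.126), CCL20 at 19.6 ± 8.65 against 50.3 ± 10.4 and CXCL5 at 12.9 ± 2.36 against 39.9 ± 6.01. Of 19 interferon response genes OASL rose, and 5 rose when adjusted over the list alone (median log2 0.07, camera adjusted p = 1.33e-05, and adjusted p = 0.0424 with an estimated correlation). The chemokine CXCL10 stood at 7.98 ± 1.21 against 1.17 ± 0.047 TPM (adjusted p = 0.377) and IFIT2 at 5.07 ± 0.196 against 1.47 ± 0.767 (adjusted p = 0.394). With a filter at 5 TPM, which left 12 members, the interferon response list had an adjusted p of 0.282, the highest of its alternatives, which began at 3.69e-08. These were the only 2 calls, of the 112 that camera made on all lists and comparisons at the preset correlation, that held with an estimated one.

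Of 20 genes of MAPK output limma called 0, with 1 adjusted over the list alone and 6 at an unadjusted p under 0.05 (camera adjusted p = 4.96e-11, and adjusted p = 0.282 with an estimated correlation). IER3, an early response gene, stood at 92.8 ± 1.58 against 196 ± 11.6 TPM (log2 -1.07, adjusted p = 0.44). The 6 tested lenvatinib targets were lower as a list with 0 called, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.000697, and adjusted p = 0.464 with an estimated correlation), with FGFR2 at 47.6 against 91.4 TPM (adjusted p = 1). At an unadjusted p under 0.05 there were 392 genes, where chance gives 682, and the groups did not overlap in 47.8% of genes, where chance gives 33.3%. The pooled spread includes the combination, whose libraries differed by a median of 0.755 (log2). The median was 0.134 with WWL70 and 0.114 in Hep3B controls. That spread is therefore too wide for this comparison, and the low count does not show that WWL70 had no effect. Without the 3 A1 libraries of lenvatinib-exposed or resistant cells 44 genes passed, and with limma's array weights 285, both chosen after seeing the data. Without either Hep3B control library 0 genes passed with limma, OASL reached an adjusted p of at most 0.0597, and 222 (without A1) or 241 (without B1) were at an unadjusted p under 0.05. Without WWL70 B1, 4 genes passed.

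Lenvatinib and WWL70 were compared with the same 2 control libraries, which give their fold changes a correlation without any effect. Across the 13645 genes, which are not independent replicates, the Pearson correlation was 0.214, where 100 draws of unchanged groups gave 0.362 (0.326 to 0.428). The covariance was 0.0276 against 0.0168 simulated (0.0146 to 0.0211), and the share of genes with the same sign was 56.7% against 62.3%. Past limma's threshold, 1 gene fell in both, where independent lists would share 0.011, and 0 rose in both. Setting each compound against a different control library was not tried, so part of the shared change may come from the controls.

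The third comparison asked how Hep3B cells differed with both compounds. APOA1 rose from 223 ± 1.20 to 6955 ± 5179 TPM (log2 4.72, SE 0.47, adjusted p = 0.000937, limma), HPX from 13.7 ± 0.337 to 387 ± 133 (log2 4.68, SE 0.29, adjusted p = 0.000173) and NPPB from 0.841 ± 1.19 to 63.4 ± 30.9 (log2 5.21, SE 0.52, adjusted p = 0.000962). DUSP6 fell from 82.0 ± 1.49 to 2.75 ± 2.33 TPM (log2 -4.62, SE 0.39, adjusted p = 0.000426). NT5E, the adenosine-producing ectonucleotidase CD73, fell from 95.0 ± 4.99 to 5.06 ± 4.06 (log2 -4.17). PPP1R1A, CBLN2 and APOC3 completed the 6 largest rises (log2 3.77, 3.64 and 3.60), and SLCO1B3 (25.9 to 0.543 TPM), LOX (65.7 to 3.75), TCIM (93.6 to 6.51) and KCNJ5 (29.3 to 1.57) the 6 largest falls. The short transcripts APOA1 and APOC3 differed between the libraries, at 10617 and 438 TPM in combination A1 and 3293 and 152 in B1. LDHA fell from 403 ± 22.2 to 260 ± 7.55 TPM (log2 -0.63, SE 0.14, adjusted p = 0.031). ABHD6 stood at 5.26 ± 2.95 against 8.08 ± 0.211 TPM (log2 -0.62, adjusted p = 0.183), FIS1 at 62.1 ± 22.3 against 50.7 ± 0.892 (adjusted p = 0.47) and DNM1L at 31.6 ± 21.4 against 45.2 ± 3.70 (adjusted p = 0.265).

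**Figure D1:**
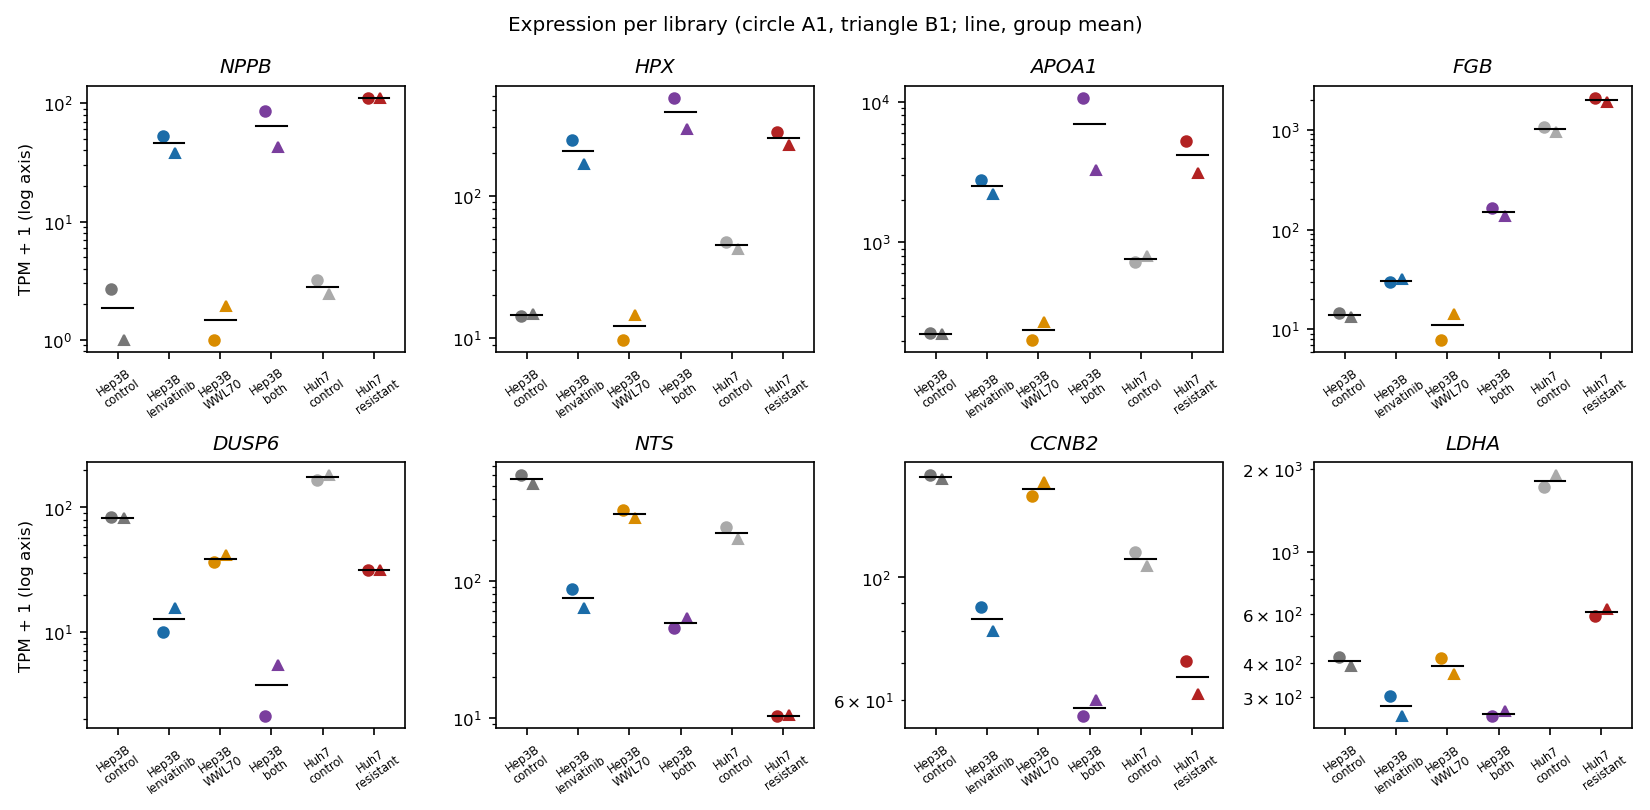
TPM + 1 on a log axis for 8 genes in the 6 groups, with a circle for library A1, a triangle for B1 and a line at the group mean. HPX rose from 13.7 TPM in Hep3B controls to 204 with lenvatinib and 387 with both compounds, and DUSP6 fell from 82.0 to 11.8 and 2.75 TPM.

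Of 22 genes of cell cycle G2 and M, 17 fell, 22 adjusted over the list alone (camera adjusted p = 6.87e-10, and adjusted p = 0.387 with an estimated correlation). CCNB1, the mitotic cyclin, fell from 188 ± 1.90 to 75.5 ± 16.1 TPM and the kinase PLK1 from 139 ± 2.41 to 46.9 ± 12.2. Of 23 DNA replication and S phase genes limma called 0, with 0 adjusted over the list alone and 6 at an unadjusted p under 0.05 (camera adjusted p = 0.904). Of 29 ATF4 and integrated stress genes 16 fell, 21 adjusted over the list alone (camera adjusted p = 1.40e-07, and adjusted p = 0.131 with an estimated correlation), including the secreted stress hormones GDF15 (161 ± 10.5 to 49.1 ± 1.86 TPM) and FGF21 (3.75 to 0.531). Of 19 chaperone and unfolded protein response genes 10 fell, 15 adjusted over the list alone (camera adjusted p = 1.19e-05, and adjusted p = 0.341 with an estimated correlation), with HSP90B1 at 378 ± 101 against 1083 ± 48.2 TPM. Of 20 genes of MAPK output 11 fell, 14 adjusted over the list alone (camera adjusted p = 1.03e-05, and adjusted p = 0.387 with an estimated correlation), with IER3 at 46.8 ± 5.24 against 196 ± 11.6. FGFR1 (27.5 to 9.82 ± 6.59 TPM), PDGFRA (23.0 to 4.30 ± 3.70) and PDGFRB (9.95 to 1.94 ± 1.92) fell among the 6 tested lenvatinib targets, 5 of which fell when adjusted over the list alone (camera adjusted p = 0.0298, and adjusted p = 0.566 with an estimated correlation). In combination A1 and B1, FGFR1 stood at 5.16 and 14.5 TPM, PDGFRA at 1.68 and 6.92, and PDGFRB at 0.579 and 3.29. With lenvatinib alone A1 and B1 held 16.3 and 14.3, 10.3 and 13.6, and 1.73 and 2.69. The transcripts of these 3 genes are 5717 to 6576 bases long, and long transcripts tended to be lower in combination A1. Without combination B1 the adjusted p of the lenvatinib targets was 0.0608, the highest of the alternatives, which began at 0.00201.

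Of 15 acute phase genes 5 rose and 1 fell, and 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.42e-05, and adjusted p = 0.276 with an estimated correlation). The 3 fibrinogen chains rose together: FGA from 60.2 ± 4.09 to 323 ± 53.6 TPM, FGB from 12.9 ± 0.916 to 149 ± 17.9 and FGG from 122 ± 15.6 to 644 ± 10.1. Without the 3 A1 libraries of lenvatinib-exposed or resistant cells the acute phase list had an adjusted p of 0.117, the highest of its alternatives, which began at 6.09e-06. Of 33 hepatocyte function genes 11 rose and 2 fell, and 12 rose and 6 fell when adjusted over the list alone (median log2 -0.02, mean 0.41, camera adjusted p = 0.000287, and adjusted p = 0.276 with an estimated correlation). That call for hepatocyte function ended with quantile normalization (adjusted p = 0.0697), with the length and GC trend removed (0.108) and without the 50 most abundant genes (0.191), and the alternatives began at 0.000129. Of 41 OXPHOS nuclear subunits NDUFC2 rose from 149 ± 7.53 to 282 ± 69.4 TPM, 0 passed when adjusted over the list alone, and the list was higher relative to all tested genes, whose median log2 change was -0.34 (camera adjusted p = 2.18e-05, and adjusted p = 0.63 with an estimated correlation). Without combination A1 the adjusted p of the OXPHOS nuclear subunits was 0.734, and the alternatives ranged from 6.42e-09 to 0.769. Of 14 fission and 12 fusion genes limma called 0, with 0 adjusted over the list alone and 4 and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.994 and 0.904).

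With both compounds 1208 genes passed, of which 333 rose and 875 fell, 858 by at least 1 on the log2 scale, and 4347 were at an unadjusted p under 0.05. The fit took the same spread for all groups. The combination libraries differed by a median of 0.755 (log2), against 0.114 in Hep3B controls. That spread is therefore too narrow for the combination, and its p-values are too small. With limma's array weights, chosen after seeing the data, 56 genes passed, and with the fit within each cell line 343. Groups did not overlap in 54.7% of genes, where chance gives 33.3%. The split depended on the scaling: it was 544 up and 611 down with median-ratio scaling, 728 and 761 with quantile normalization and 389 and 549 without the 50 most abundant genes, which shifted the median log2 change of all genes by 0.39, 0.38 and 0.12. The count was 195 or 187 without Hep3B control A1 or B1, 733 or 735 without either lenvatinib library, 655 or 652 without either WWL70 library, 622 or 623 without either Huh7 control library and 8669 without combination B1. Of 35 named genes past the threshold, 30 stayed past it with each library left out in turn, and FGFR1, LDHA, NDUFC2, PDGFRA and PDGFRB did not.

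**Figure D2:**
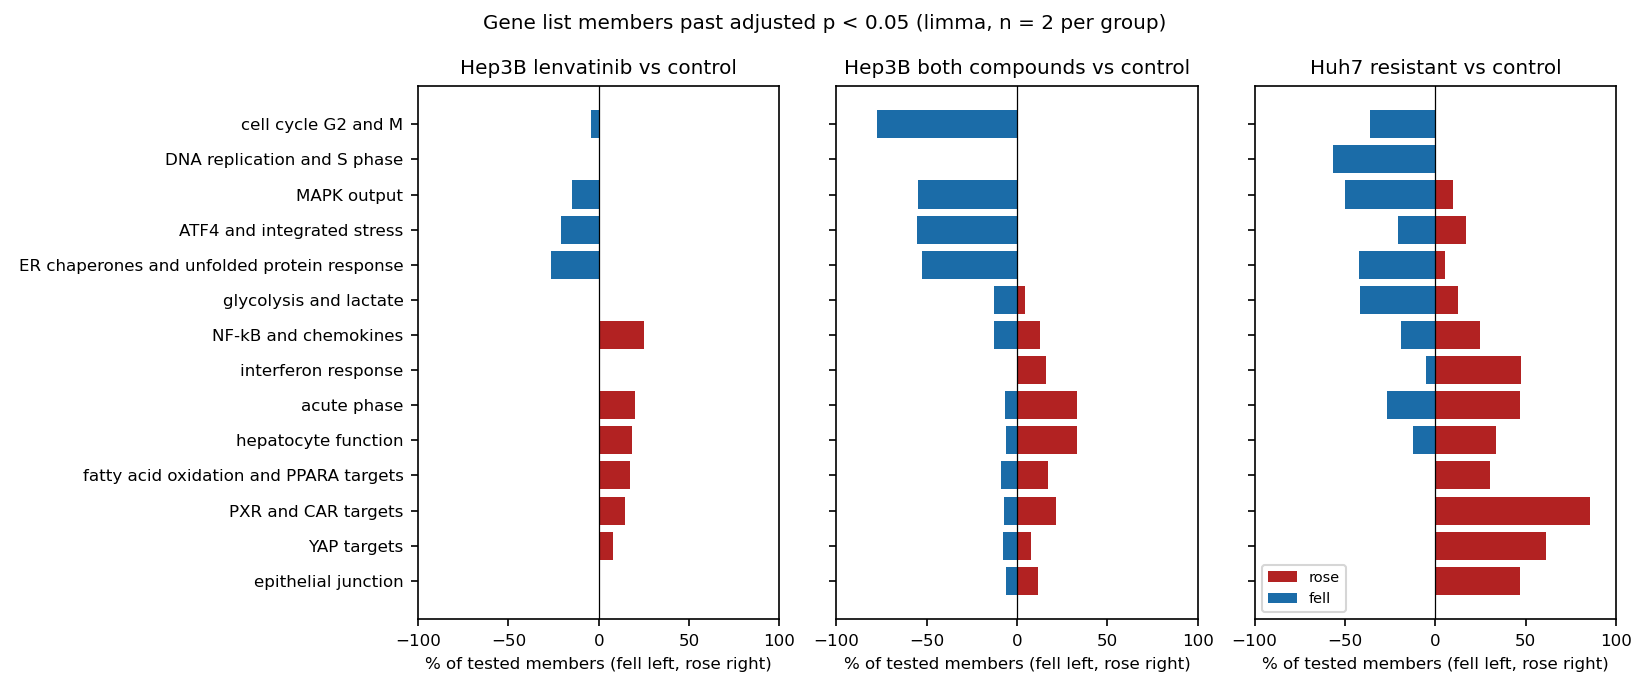
Percent of tested members of 14 gene lists that rose (right, red) or fell (left, blue) past the threshold in Hep3B cells with lenvatinib, Hep3B cells with both compounds and resistant Huh7 cells, each against its control. Of 22 G2 and M phase genes, 1, 17 and 8 fell in these comparisons.

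The combination was then set against lenvatinib alone, to ask what WWL70 added. The labels do not give the lenvatinib dose of the combination. A difference here may therefore follow WWL70 or a different lenvatinib dose. The passing genes that are listed under a symbol were fibrinogen genes. FGB (chromosome 4, 154562956 to 154571086) rose from 29.7 ± 1.57 to 149 ± 17.9 TPM (log2 2.29, SE 0.26, adjusted p = 0.0444, limma) and FGG (chromosome 4, 154604134 to 154612967) from 267 ± 4.21 to 644 ± 10.1 (log2 1.27, SE 0.13, adjusted p = 0.0412). FGA stood at 323 ± 53.6 against 149 TPM (log2 1.10, adjusted p = 0.0767). The third gene, ENSG00000285508 (chromosome 20, 10413520 to 10431922), named after its values were seen, stood at 4.02 ± 1.05 TPM and is listed at 0 in both lenvatinib libraries (adjusted p = 0.00149). It lies inside the gene MKKS on the same strand, so its level is uncertain. ABHD6 stood at 5.26 ± 2.95 against 7.84 ± 0.193 TPM (log2 -0.58, adjusted p = 0.456), and LDHA at 260 ± 7.55 against 279 ± 31.3 (log2 -0.09, adjusted p = 0.701). FIS1 and DNM1L differed by log2 0.08 and -0.52 (adjusted p = 0.852 and 0.51).

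Cell cycle and MAPK genes were lower as groups, although limma called 0 members of either over all genes. Of 22 genes of cell cycle G2 and M, 11 fell when adjusted over the list alone and 13 were at an unadjusted p under 0.05 (camera adjusted p = 1.23e-07, and adjusted p = 0.407 with an estimated correlation). PLK1 stood at 46.9 ± 12.2 against 83.0 TPM (adjusted p = 0.225). Of 20 genes of MAPK output, 12 fell when adjusted over the list alone and 12 at an unadjusted p under 0.05 (camera adjusted p = 5.52e-07, and adjusted p = 0.226 with an estimated correlation), with DUSP6 at 2.75 ± 2.33 against 11.8 ± 4.06 TPM and IER3 at 46.8 ± 5.24 against 107. Of 15 acute phase genes 2 rose, and 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 5.52e-07, and adjusted p = 0.206 with an estimated correlation). Without combination A1 the adjusted p of the acute phase list was 0.345, and the alternatives ranged from 1.04e-07 to 0.389. Relative to all tested genes, whose median log2 change was -0.29, the 33 cytosolic ribosomal proteins were higher with 0 called, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 7.48e-16, and adjusted p = 0.424 with an estimated correlation), with RPS19 at 1593 ± 1081 against 818 ± 210 TPM. Without combination A1 the direction of the cytosolic ribosomal proteins turned to down (adjusted p = 0.491, the highest of the alternatives, which began at 6.04e-22).

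Between the combination and lenvatinib 3 genes passed, all 3 upward, and 1518 were at an unadjusted p under 0.05. With the replicate letter as a block 1 of them passed, and the calls of FGB and FGG ended. The groups did not overlap in 27.9% of genes, where chance gives 33.3%, and in both groups A1 deviated from B1 in the same genes (correlation across genes 0.681), which the test counts as spread. The count was 1 without either Hep3B control library, lenvatinib B1 or either Huh7 control library, 5 without combination A1, and 7826 without combination B1. It was 2 without either resistant library. FGB reached an adjusted p of 0.340 and so did FGG when libraries were left out in turn, and they stayed past the threshold in 3 and 2 of the 12 fits, while ENSG00000285508 stayed past it in 12. With median-ratio scaling or quantile normalization limma called 0 genes, with 1137 and 1187 at an unadjusted p under 0.05.

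Against WWL70 alone, which asks what lenvatinib added, NPPB, HPX and APOA1 led the rises. NPPB rose to 63.4 ± 30.9 TPM (log2 5.45, adjusted p = 0.00109, limma), HPX to 387 ± 133 (4.98, adjusted p = 0.000202) and APOA1 to 6955 ± 5179 (4.66, adjusted p = 0.00141). NT5E (log2 -3.99), SLCO1B3 (-3.98) and HAL, which degrades histidine (-3.55), were the largest falls. LDHA fell from 389 ± 37.9 to 260 ± 7.55 TPM (log2 -0.58, adjusted p = 0.0453), and ABHD6 stood at 5.26 ± 2.95 against 10.4 ± 0.434 (log2 -0.95, adjusted p = 0.0838). FIS1 and DNM1L differed by 0.37 and -0.62 (adjusted p = 0.277 and 0.30). Of 22 G2 and M phase genes 15 fell, 22 adjusted over the list alone (camera adjusted p = 1.70e-09, and adjusted p = 0.47 with an estimated correlation). Of 16 NF-kB and chemokine genes 6 rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 5.32e-07, and adjusted p = 0.153 with an estimated correlation). In all 1078 genes passed, 325 up and 753 down, with 562 and 550 under median-ratio scaling, 746 and 725 under quantile normalization and 360 and 502 without the 50 most abundant genes. The shared spread is too narrow for the combination here too. With limma's array weights 18 genes passed, and with the fit within each cell line 207. The count was 495 without either Hep3B control library, 570 or 579 without either lenvatinib library, 100 or 174 without WWL70 A1 or B1, 504 without either Huh7 control library, 705 or 706 without either resistant library and 8593 without combination B1. LDHA lost its call when libraries were left out, and the other 6 named genes kept it.

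The interaction asked whether the effects of both compounds added up on the log2 scale, which rests on a lenvatinib dose in the combination that the labels do not give. ENSG00000285508 passed (adjusted p = 0.0282, limma). It is listed at 0 in the 10 libraries outside the combination, so the size of its difference rests on the pseudocount, and it passed in 5 of 25 alternatives. ABHD6 (-0.91, adjusted p = 0.766), FIS1 (0.21, adjusted p = 0.805), DNM1L (-0.46, adjusted p = 0.778) and LDHA (-0.04, adjusted p = 0.943) did not pass. The acute phase list was higher than additive, with limma calling 0 members, 4 adjusted over the list alone and 6 at an unadjusted p under 0.05 (median log2 0.51, camera adjusted p = 4.11e-10, and adjusted p = 0.205 with an estimated correlation). The G2 and M phase list was lower, with 0 called, 0 adjusted over the list alone and 7 at an unadjusted p under 0.05 (median log2 -0.86, camera adjusted p = 1.37e-05, and adjusted p = 0.707 with an estimated correlation). At an unadjusted p under 0.05 there were 698 genes, where chance gives 682. The count was 3 without lenvatinib A1, 2 without WWL70 B1, 6063 without combination B1, and 0 with limma without each of the other 9 libraries, with 292 to 940 genes at an unadjusted p under 0.05.

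The next comparison asked how lenvatinib-resistant Huh7 cells differed from Huh7 controls. Whether the resistant cells were under the drug at harvest is not in the labels. SLC7A7, an amino acid transporter of absorptive epithelia, rose from 7.91 ± 0.725 to 477 ± 43.5 TPM (log2 5.74, adjusted p = 1.60e-06, limma). APOA4 (log2 5.46), NPPB (5.30) and the glutathione transferase GSTA2 (5.17) were also among the 6 largest rises. THBS4, a matrix glycoprotein, fell from 152 ± 11.1 to 2.83 ± 0.759 TPM (log2 -5.33, adjusted p = 5.90e-06). NTS fell from 224 ± 32.7 to 9.33 ± 0.11 TPM (log2 -4.44, SE 0.20, adjusted p = 3.71e-06), and SLC6A14 (-4.22) and NPTX2 (-4.17) were also among the 6 largest falls.

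LDHA fell from 1812 ± 132 to 606 ± 24.9 TPM in resistant cells (log2 -1.58, SE 0.14, adjusted p = 0.000101, limma). Of 24 tested genes of glycolysis and lactate, 10 fell and 3 rose, and 14 fell and 3 rose when adjusted over the list alone (median log2 -0.74, camera adjusted p = 0.0168, and adjusted p = 0.28 with an estimated correlation). The glucose transporter SLC2A1 (94.6 to 39.0 TPM), HK2 (45.4 to 17.5), ENO1 (2193 ± 28.5 to 947 ± 143) and PKM (1526 ± 52.3 to 831 ± 27.4) fell. Among the 3 that rose were SLC2A2, the liver glucose transporter (0.90 to 25.1 TPM), and SLC2A3 (0.036 to 2.69). With median-ratio scaling the adjusted p of glycolysis and lactate was 0.07, the highest of the alternatives, which began at 0.00558. ABHD6 stood at 8.48 ± 0.408 against 5.78 ± 0.291 TPM (log2 0.48, SE 0.30, adjusted p = 0.321). DNM1L stood at 47.7 ± 14.9 against 75.6 ± 0.486 TPM (adjusted p = 0.304) and FIS1 at 97.2 against 91.6 (adjusted p = 0.868). Of 14 fission genes MIEF2 rose (6.82 to 13.2 TPM, camera adjusted p = 0.946), and of 12 fusion genes limma called 0, with 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.249). Of 41 OXPHOS nuclear subunits 1 fell (camera adjusted p = 0.726). Of 18 monoacylglycerol and endocannabinoid hydrolases 6 rose, also 6 adjusted over the list alone (camera adjusted p = 0.00675, and adjusted p = 0.25 with an estimated correlation), including ABHD12 (91.7 ± 11.5 to 196 ± 22.1 TPM), MGLL (54.6 to 96.3), CES1 (7.30 to 31.8) and FAAH (0.607 to 3.18).

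In resistant cells, of 23 DNA replication and S phase genes 13 fell, 17 adjusted over the list alone (camera adjusted p = 3.93e-07, and adjusted p = 0.28 with an estimated correlation), with the helicase subunit MCM7 at 274 ± 23.7 against 554 ± 15.7 TPM and PCNA at 254 ± 28.6 against 451 ± 10.7. Of 22 G2 and M phase genes 8 fell, 18 adjusted over the list alone (camera adjusted p = 3.93e-07, and adjusted p = 0.36 with an estimated correlation), with PLK1 at 65.1 ± 3.14 against 124 ± 0.605 TPM. Of 20 genes of MAPK output 10 fell and 2 rose, and 11 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.000471, and adjusted p = 0.36 with an estimated correlation). DUSP6 fell from 174 ± 12.5 to 30.5 ± 0.163 TPM, ETV4 from 156 to 37.6 and EGR1 from 17.1 to 2.24, while DUSP4 (9.48 to 22.7) and PHLDA1 (6.57 to 33.3) rose. FGFR1 fell from 37.6 ± 0.891 to 7.69 ± 1.76 TPM (log2 -2.17, SE 0.38, adjusted p = 0.00399) and FGFR4 from 314 ± 10.6 to 224 (log2 -0.48, adjusted p = 0.0264). Among 11 ERBB receptors and ligands 4 rose, 4 adjusted over the list alone (camera adjusted p = 0.0275, and adjusted p = 0.509 with an estimated correlation), including the ligands AREG (2.67 to 30.1 TPM) and NRG1 (1.68 to 14.5). Without resistant B1 the adjusted p of the ERBB receptors and ligands was 0.124 and with no filter on low values it was 0.0535, and the alternatives began at 0.00438.

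In resistant cells, of 14 PXR and CAR targets, the xenobiotic response genes, 12 rose, and 12 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.93e-07, and adjusted p = 0.142 with an estimated correlation). GSTA1 rose from 14.6 ± 0.875 to 479 ± 131 TPM, SULT2A1 from 23.8 to 113 ± 12.4, and ABCB1, the efflux pump P-glycoprotein, from 26.2 ± 2.63 to 157 ± 29.2. Of 11 drug efflux transporters 2 rose and 2 fell, ABCC1 among the latter (8.53 to 3.43 TPM, camera adjusted p = 0.553). Of 13 YAP targets 8 rose, 8 adjusted over the list alone (camera adjusted p = 8.93e-06, and adjusted p = 0.36 with an estimated correlation), with ANKRD1 at 248 ± 3.95 against 9.49 ± 3.91 TPM. Of 17 epithelial junction genes 8 rose, 11 adjusted over the list alone (camera adjusted p = 2.97e-05, and adjusted p = 0.203 with an estimated correlation), including JUP (64.6 ± 4.15 to 249 ± 12.3 TPM) and CLDN7 (0.791 to 19.1). Of 20 mesenchymal and TGF beta genes 9 rose and 2 fell, and 10 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.00235, and adjusted p = 0.325 with an estimated correlation), with the filament gene VIM at 1440 ± 81.5 against 209.9 ± 23.9 TPM.

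Among 10 MHC class I presentation genes 6 rose, 6 adjusted over the list alone (camera adjusted p = 0.000389, and adjusted p = 0.203 with an estimated correlation), with TAPBP at 50.1 against 16.2 TPM and B2M at 902 ± 112 against 463. Of 19 interferon response genes 9 rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000446, and adjusted p = 0.142 with an estimated correlation), with MX1 rising from 2.32 to 16.8 TPM and MX2 falling from 92.2 to 47.1. Of 29 autophagy, mitophagy and lysosome genes 13 rose and 1 fell, and 15 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00196, and adjusted p = 0.36 with an estimated correlation). CTSB (224 to 450 TPM), NEU1 (44.0 to 246) and PINK1 (18.0 to 35.5) rose and BNIP3 (222 to 128) fell. BCL2L1, which restrains apoptosis, rose from 203 ± 15.5 to 375 TPM and PMAIP1, which promotes it, fell from 7.20 to 1.48, while the lists of genes promoting and restraining apoptosis had camera adjusted p-values of 0.946 and 0.908. Among markers of other cell types, 6 of 8 biliary markers rose and 1 fell, and 6 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0125, and adjusted p = 0.219 with an estimated correlation). KRT19 was at 415 ± 95.3 against 54.4 ± 16.3 TPM and EPCAM at 221 against 28.4. Of 6 tested fibroblast markers 3 rose, 3 adjusted over the list alone (camera adjusted p = 0.0167, and adjusted p = 0.36 with an estimated correlation): COL3A1 (0.58 to 9.07 TPM), COL1A1 (0.687 to 7.05) and LUM (0.795 to 6.66). Of 3 tested leukocyte markers 1 rose and 1 fell (camera adjusted p = 0.733).

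Between resistant and control Huh7 cells 2579 genes passed, 1674 up and 905 down, 1691 of them by at least 1 on the log2 scale, with 4247 at an unadjusted p under 0.05. The groups did not overlap in 67.6% of genes, where chance gives 33.3%. Libraries differed by a median of 0.324 (log2) in resistant cells and 0.115 in Huh7 controls, against 0.755 in the combination. The pooled spread is therefore wide here too, and a gene that did not pass is not shown to be unchanged. With quantile normalization 1735 rose and 1647 fell, and median-ratio scaling shifted the median of all genes by 0.12. The count was 1256 or 1249 without Huh7 control A1 or B1, 1442 or 1682 without resistant A1 or B1, and 5422 or 5426 without combination A1 or B1. Of 92 named genes past the threshold 74 stayed past it with each library left out in turn, and among those that did not were APOA1 (10 of 12 fits, adjusted p up to 0.068), CCNB1, PLK1, HK2, SLC2A1, ABCC1, FGFR4, FAAH, MGLL, MIEF2, PINK1 and BNIP3.

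The last comparison set the lenvatinib response of Hep3B beside the resistance difference of Huh7, which share no libraries but differ in cell line, exposure and resistance together. In this overlap 123 genes rose in both, where independent lists would share 23.1, and 51 fell in both, where 9.95 would (Fisher's exact test, one-sided, p = 1.50e-66 and 1.51e-23). That test treats genes as independent, which they are not. Both lists came from the same fit with a shared spread per gene. The A1 libraries of both groups also shared a deviation (correlation across genes 0.616). These p-values therefore do not measure replication. NPPB, HPX (43.8 ± 3.43 to 250.0 ± 36.0 TPM in Huh7), APOA1 (762 ± 52.6 to 4185 ± 1519), APOC3 (32.3 to 238) and LYPD1 rose in both, and NTS, DUSP6, SLCO1B3 and HAL fell in both. With libraries left out in turn, HPX, LYPD1, NTS and SLCO1B3 stayed past the threshold in both comparisons in each of the 12 fits, while the lenvatinib calls of APOA1, APOC3, DUSP6 and HAL stayed in 8 and that of NPPB in 11. In 19 genes the directions were opposite, among them BCL2L1, NRG1, RASD1 (18.7 to 7.63 TPM in Hep3B and 2.27 to 31.7 in Huh7) and SPINK1. The lenvatinib calls of BCL2L1, RASD1, NRG1 and SPINK1 stayed in 2, 4, 8 and 11 of the 12 fits, and their resistance calls in 12. NRG1 was low in Hep3B, at 1.77 and 2.36 TPM in the control libraries and 0.31 and 0.178 with lenvatinib. SPINK1, a secreted trypsin inhibitor, fell from 8.64 ± 0.878 to 0.306 ± 0.433 TPM in Hep3B and rose from 190.4 ± 25.9 to 719.7 ± 197 in Huh7. Across the 13645 genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was 0.43 and the Spearman correlation 0.456. The counts moved with the libraries: without Hep3B control A1 or B1, 13 or 12 rose and 5 or 4 fell in both, and without lenvatinib A1 or B1, 11 or 19 rose and 4 or 6 fell. Without either WWL70 library 66 rose and 30 fell, without Huh7 control A1 or B1 42 or 43 rose and 22 or 20 fell, and without resistant A1 or B1 68 or 72 rose and 31 fell. Without combination A1 or B1, 468 or 469 rose and 444 or 440 fell, and without the 3 A1 libraries of lenvatinib-exposed or resistant cells, chosen after seeing the data, 687 rose and 859 fell, where independent lists would share 269.5 and 350. With the B1 libraries of the lenvatinib and the resistant group alone the correlations were 0.379 and 0.392, and with the A1 libraries 0.495 and 0.532.

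**Figure D3:**
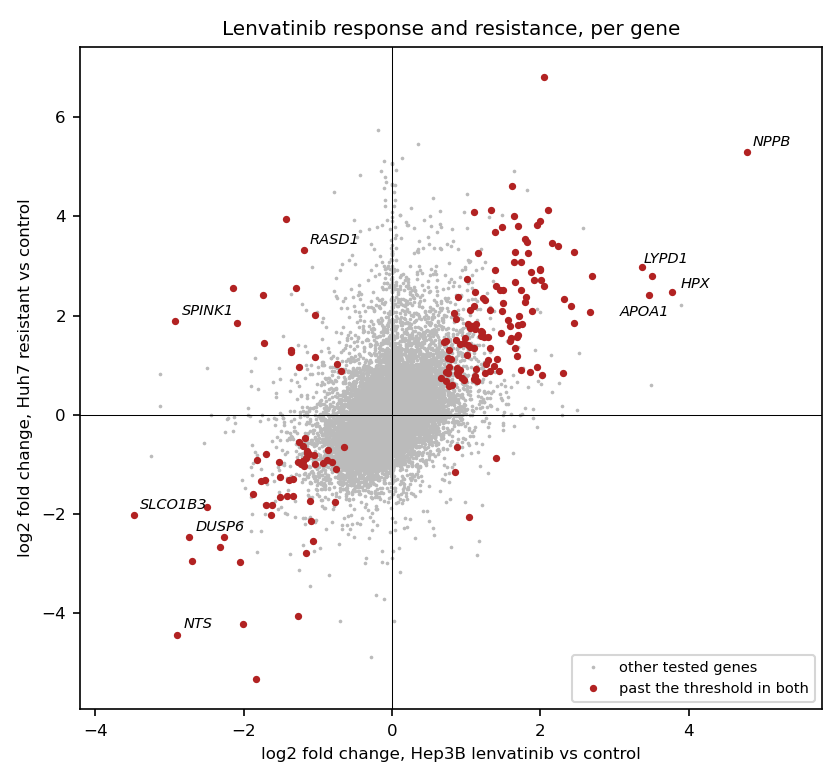
Log2 fold change of each tested gene in Hep3B with lenvatinib (horizontal axis) against that in resistant Huh7 cells (vertical axis), each against its control, with genes past the threshold in both in red. Of those, 123 rose in both, 51 fell in both and 19 moved in opposite directions.

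The 2 effects differed in 860 genes, 693 with a higher value in resistance and 167 with a lower one, and 2373 were at an unadjusted p under 0.05. LDHA was lower in resistance by a difference of -1.04 (SE 0.20, adjusted p = 0.0171, limma), while ABHD6 (0.52, adjusted p = 0.661), APOA1 (-1.06, adjusted p = 0.521), DUSP6 (0.26, adjusted p = 0.927) and CCNB2 (0.14, adjusted p = 0.866) did not pass. Of 23 DNA replication and S phase genes 5 were lower in resistance, 14 adjusted over the list alone (camera adjusted p = 6.11e-10, and adjusted p = 0.278 with an estimated correlation). Of 29 ATF4 and integrated stress genes 4 were higher, 8 adjusted over the list alone (camera adjusted p = 6.72e-05, and adjusted p = 0.278 with an estimated correlation). With quantile normalization 754 were higher and 405 lower. The count was 454 or 465 without Hep3B control A1 or B1, 484 or 487 without lenvatinib A1 or B1, 498 or 519 without Huh7 control A1 or B1, and 2240 or 2245 without combination A1 or B1. At the preset correlation camera called 12 of 49 lists with lenvatinib, 11 with WWL70, 13 with both compounds, 16 for the combination against lenvatinib, 10 against WWL70, 10 for the interaction, 23 in resistance and 17 for this difference.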

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

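Chosen only after the result was seen were the test of a batch shared by all A1 libraries and both tests of the agreement between the lenvatinib response and resistance.

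The resistance difference in Huh7 differed from the lenvatinib response in Hep3B for 860 genes, by limma's test of the difference between the effects. BCL2L1, which restrains apoptosis, was higher in resistance by a difference of 1.57 (SE 0.19, adjusted p = 0.00156). The growth factor gene NRG1 differed by 3.84 (SE 0.31, adjusted p = 0.000221), RASD1 by 4.52 (SE 0.29, adjusted p = 7.59e-05) and SPINK1 by 4.81 (SE 0.45, adjusted p = 0.000394). LDHA differed by -1.04 (SE 0.20, adjusted p = 0.0171) and NTS by -1.55 (SE 0.29, adjusted p = 0.0134). LDHA had not passed with lenvatinib in Hep3B (adjusted p = 0.114). Cell line, exposure and resistance all differ between these effects, so the test does not say which of them a difference follows. In Hep3B, the test of whether WWL70 acted differently with lenvatinib than without called 1 gene, ENSG00000285508, with a fitted difference of 2.31 (adjusted p = 0.0282). ENSG00000285508 is listed at 0 outside the combination, so this size rests on the pseudocount: it ranged from 0.85 to 5.34 over 25 alternatives, of which 5 called it, and it passed in 1 of the 12 fits that left out a library.

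The A1 libraries of Hep3B with lenvatinib, Hep3B with both compounds and resistant Huh7 deviated from their B1 partners in the same genes, with correlations across genes of 0.681, 0.616 and 0.739. Transcript length and GC content accounted for 30.7%, 49.9% and 37.7% of these deviations, but after that trend was removed the lowest correlation was still 0.431. The trend as fitted was therefore not the whole of the shared deviation. It used the longest annotated transcript of each gene, which need not be the expressed one. The removal therefore cannot exclude length or GC content as the whole cause. A batch shared by all A1 libraries is argued against by the control and WWL70 groups, whose A1 deviations correlated with these by at most 0.0671. A stronger lenvatinib response in A1 as the source of the deviation across all tested genes is argued against. The deviations correlated with the response of another group on its B1 libraries by at most 0.076. That correlation runs over 13645 genes, of which 338 passed with lenvatinib. It therefore cannot decide whether the responding genes changed more in A1. A stronger response of those genes, a common state of these 3 cultures or a common handling of these 3 libraries could remain. None of these was tested.

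Genes that rose or fell with lenvatinib in Hep3B tended to do so in resistant Huh7 (NPPB, HPX and APOA1 up, NTS and DUSP6 down), with a correlation across genes of 0.43. With only the B1 libraries of the lenvatinib and the resistant group it was 0.379, which argues against the shared A1 deviation as the whole cause. After the length and GC trend was removed it was 0.380, so the trend as fitted was not the whole of the agreement. That trend used the longest annotated transcript, so the removal cannot exclude length or GC content either. Of the genes past the threshold, 298 rose and 266 fell in both after that removal, where independent lists would share 81.3 and 94.3. A hypothesis is that the resistant cells were under lenvatinib or kept part of its response, which may be asked of cells whose exposure at harvest is known, and was not tested here.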

How the results depend on the processing

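With 2 libraries per group and unknown depth, the number of genes past the threshold moved with many of the alternatives. Over 279 pairs of a named gene and a comparison, 7235 values under the alternatives gave 0 changes of sign in a gene past the threshold before or after, 6607 on the same side of the threshold, 476 that lost the call and 152 that gained it. Genes not past the threshold did change sign: among them were DNM1L with both compounds against control (log2 -1.40 to 0.05) and against lenvatinib (-1.24 to 0.21), and, against lenvatinib, FIS1 (-0.30 to 0.45) and LDHA (-0.21 to 0.22). The alternatives chosen after seeing the data were leaving out the 3 A1 libraries of lenvatinib-exposed or resistant cells, limma's array weights and removal of the length and GC trend. Of the genes past the threshold, removing the trend retained 301 of 338 with lenvatinib, 1006 of 1208 with both compounds and 2309 of 2579 in resistance. Leaving out those 3 libraries left 1 library in each of their groups. The error then came only from the other groups, whose libraries differed least. The calls kept there therefore do not speak for robustness. Lone libraries in such fits were assumed to vary like the other groups. The difference between resistance and lenvatinib spans both lines and could not be fitted within a line. Except where the fit had fewer libraries or genes by construction, the cause of these changes was not tested.

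Counts of genes past the threshold that moved by over 1.5 times were as follows, against 338 with lenvatinib, 2 with WWL70, 1208 with both compounds, 3 for the combination against lenvatinib, 1078 against WWL70, 1 for the interaction, 2579 in resistance, 860 for the difference between resistance and lenvatinib, and 1 in the overlap of lenvatinib and WWL70. With pseudocount 0.1 they were 225 with lenvatinib, 1 with WWL70 and 0 in the overlap, and with pseudocount 5 they were 7 against lenvatinib, 0 for the interaction and 2 in the overlap. With no filter on low values they were 5 with WWL70, 13 against lenvatinib and 2 for the interaction, and with TPM of at least 5 in 2 libraries they were 0 in these 3. Median-ratio scaling gave 0 against lenvatinib and 0 for the interaction, as did quantile normalization, which also gave 573 with lenvatinib. These scalings shifted the median log2 change of all genes by 0.30 and 0.32 against lenvatinib, 0.38 and 0.37 against WWL70, and 0.29 and 0.31 for the interaction. limma without trend gave 1 against lenvatinib and 0 for the interaction, and robust hyperparameters gave 1 against lenvatinib. The fit within each cell line gave 81 with lenvatinib, 343 with both compounds, 207 against WWL70 and 0 for the interaction. An adjusted p under 0.01 gave 80, 327, 1 and 246 with lenvatinib, both compounds, against lenvatinib and against WWL70, 0 for the interaction, 1340 in resistance and 427 for the difference, and an absolute log2 fold change of at least 1 left 1691 in resistance.

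Without the 3 A1 libraries of the lenvatinib-exposed groups the counts were 2634 with lenvatinib, 44 with WWL70, 3441 with both compounds, 25 against lenvatinib, 3494 against WWL70, 5 for the interaction, 6462 in resistance, 3317 for the difference and 26 in the overlap. limma array weights gave 2249, 285, 56, 0, 18, 0, 4407 and 1972 in that order, with a weight of 0.102 for both combination libraries. With the length and GC trend removed per library they were 1013 with lenvatinib, 2442 with both compounds, 24 against lenvatinib, 2504 against WWL70, 0 for the interaction, 4739 in resistance and 1914 for the difference. Where limma called 0 at an adjusted p under 0.05, the genes at an unadjusted p under 0.05 were 248 for WWL70 at TPM 5, 189 to 1287 against lenvatinib and 207 to 1170 for the interaction. The 112 list calls became 2 with camera's estimated correlation and 187 with fry's mixed test.

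The labels do not say that A1 or B1 marks a shared culture or day, and the names did not pair the samples across all 6 groups. Deviations of A1 from B1 correlated by 0.616 to 0.739 among the 3 lenvatinib-exposed or resistant groups. In the other pairs of groups they correlated by -0.124 to 0.0671. The block left 1 of the 3 genes called against lenvatinib, ENSG00000285508 (adjusted p = 0.0198), and FGB and FGG had an adjusted p of 0.225. A block for those 3 groups alone was not fitted. With the replicate block the counts were 95 with lenvatinib, 641 with both compounds, 1 against lenvatinib, 464 against WWL70 and 0 for the interaction (540 at an unadjusted p under 0.05), and 109 of the list tests.

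With each library left out in turn the counts ranged from 28 to 1649 with lenvatinib, 0 to 4 with WWL70, 187 to 8669 with both compounds, 1 to 7826 against lenvatinib, 100 to 8593 against WWL70, 0 to 6063 for the interaction, 1249 to 5426 in resistance, 454 to 2245 for the difference, 0 to 3 in the overlap and 100 to 114 list calls. The highest count of genes in each comparison but that of WWL70 was without a combination library.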

Other observations

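Chosen only after the result was seen was the test of abundant enterocyte transcripts.

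Genes of the intestinal absorptive cell stood among the largest rises of the resistant Huh7 cells. After APOA4 and others were seen there, a list of 28 other enterocyte genes and one of 13 intestinal identity genes were written, with no gene from the lists fixed earlier. Of the 21 enterocyte genes tested, 15 rose and 1 fell over all genes, and 17 rose when adjusted over the list alone (median log2 2.06, limma camera p = 6.24e-13, and p = 0.0109 with an estimated correlation). The other 7 were below the filter on low values, which keeps a gene that rises from near 0, and among them FABP2 stood at 0.898 TPM and SLC5A1 at 0.013 in resistant cells. Of the identity genes, the transcription factor gene CDX2 rose from 13.2 ± 0.589 to 50.1 ± 10.2 TPM (log2 1.83, adjusted p = 0.000584, n = 2). The cadherin CDH17 (34.1 ± 2.88 to 377 ± 52.7 TPM) and GUCY2C (9.82 to 85.7), of the same list, rose as well. Of the enterocyte list, those that rose included the peptidase DPP4 (59.6 ± 3.71 to 494 ± 84.7 TPM), lactase LCT (0.617 to 16.0), the phosphatase ALPI (1.17 to 19.5), the receptor CUBN (0.502 to 22.0) and the retinol-binding RBP2 (54.3 to 451 ± 144). MGAM, a brush border glucosidase, fell from 3.13 to 1.36 TPM, and VIL1 (193 to 425, adjusted p = 0.0505) and MTTP (196 to 255, adjusted p = 0.526) did not pass. Controls already held CDX2, CDH17, DPP4 and VIL1 above 10 TPM. In Hep3B with lenvatinib, limma called 1 of the 21, SLC6A19, which fell.

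Some other genes, named here after their values were seen, moved in different directions in resistant cells. They were not tested as a group. CPS1, which starts the urea cycle, rose from 3.42 to 56.2 TPM, and ARG1, which ends it, fell from 163 to 16.1. CIDEC of lipid droplets rose from 1.74 to 62.7 TPM. The fetal and progenitor genes DLK1 (15.7 to 0.317 TPM) and LGR5 (12.3 to 1.78) fell, although 6 members of the oncofetal list rose and 2 fell (camera adjusted p = 0.651).

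That a wider set of enterocyte genes is higher in resistant Huh7 was borne out by the 15 of 21 that rose, in a test written before their values were seen but on a theme found in the same data. FABP2, KRT20, LGALS4 and SLC5A1, abundant transcripts of enterocytes, rose by at most 0.951 TPM where the tested enterocyte genes rose by a median of 18.3. They were chosen after the result was seen, and other intestinal transcripts such as RBP2 and CDH17 rose. They therefore cannot decide whether intestinal epithelial cells mixed into the cultures were the source of the rise. The identity genes left such cells open too. Of 13 intestinal identity genes 7 were under 1 TPM in both controls. Of these, 2 (CEACAM6 and FXYD3) reached 1 TPM in both resistant libraries and 1 reached 5, between the bounds set for either answer. CDX1, CEACAM5 and OLFM4 are listed at 0 in resistant cells, KRT20 stood at 0.302 TPM, LGALS4 at 0.424, AGR2 at 9.80 against 16.5 in controls, and TFF3 at 28.7 against 2.19. A candidate explanation is a partly intestinal program within resistant Huh7 cells, for which the tables hold no test at the level of single cells.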
